A study of Drosophila melanogaster with 8 samples.

How the data were processed

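Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map the DNA bound by Bicoid (Bcd) in Drosophila melanogaster embryos collected 1 to 3 h after egg laying. The 8 samples fell into 4 groups of 2 replicates: wild-type Bcd ChIP, wild-type input, zelda mutant Bcd ChIP and zelda mutant input. Per the labels' protocols, embryo homogenates were fixed with formaldehyde and sonicated, immunoprecipitated with a polyclonal rabbit antiserum against Bcd, and made into barcoded libraries. The input libraries carried no antibody enrichment. Nothing in the labels says whether the 2 replicates of a group came from separate embryo collections.

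The authors deposited 1 peak list per genotype, each named in the labels of both Bcd ChIP replicates of that genotype. Per the submitters' processing notes, reads were processed with Bowtie2 against the build dm3, and peaks came from MACS 1.4.2. Per the file headers, each run used 1 ChIP file and 1 control file, a tag size of 50 bp, a band width of 300 bp, a fragment size of 200 bp, an effective genome size of 1.52e+08 bp and a p cutoff of 1e-05. At most 1 tag was kept per position, and the larger dataset was scaled towards the smaller one. How the replicates were joined into 1 ChIP file is not given in the sources used here.

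Per the file headers, each peak has a tag count (whole ChIP tags inside the peak, not normalized), a score (−10 times the log10 of the MACS p-value), a fold enrichment (a ratio of ChIP signal to the local background expected from the control) and an empirical false discovery rate in percent (FDR, from exchanging ChIP and control). The deposited score and fold enrichment are the authors' own values of each peak. They were used to rank or describe peaks within a list, since MACS scaled the 2 lists to different depths. No peak in either list had a score below 50, the score at the p cutoff. The highest FDR was 17.3% in the wild-type list and 13.9% in the mutant list, so the lists hold peaks that MACS itself rated as uncertain. The score was exactly 3100 for 13 wild-type peaks, so their order by score is undefined.

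The depth differed between the genotypes. After removal of duplicate tags, the headers gave 39154546 ChIP tags for wild type and 10060479 for the mutant, a ratio of 3.89. The control held 22487837 tags for wild type and 17035242 for the mutant. A deeper library gives longer and more peaks at a fixed p cutoff. Sequencing tags are not independent molecules, so all intervals below cover counting error only.

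Positions are 1-based on dm3, and a summit was placed at the peak start plus its offset minus 1. Chromosomes were grouped into arms (2L, 2R, 3L, 3R, 4 and X), the heterochromatic scaffolds of the assembly (Het) and its unplaced sequences (U and Uextra). A peak was called shared when it overlapped a peak of the other list by at least 1 bp (bedtools 2.31.1), and otherwise wild-type-only or mutant-only. Observed overlaps were set beside 1000 random placements of the other list, in which every peak moved to a random place on its own chromosome up to the last peak end found in either list. Median strengths of shared and unshared peaks were compared within a list, and the difference was placed among 10000 random splits of the same sizes. Shares have Wilson 95% intervals. Tag counts of single peaks have exact Poisson 95% intervals. With 1 list per genotype there is no replicate spread, so no p-value is given for a difference between the genotypes; percentiles describe these lists.

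The named peaks follow a rule set before the data were examined: the 10 peaks with the highest fold enrichment among the shared (ranked by wild-type fold), the wild-type-only and the mutant-only peaks. The rule also covered 11 lists of genes, the position of peaks relative to genes, and the sequence motifs of Zelda and Bcd. These parts were not run, because the gene table at hand is for Release 6 of the genome, positions were not carried over from one build to another, and a dm3 genome or annotation was not used here. Peaks are therefore named by position and not by gene. Alternatives set in the same way were a reciprocal overlap of 50%, summits within 200 bp, stricter score or fold thresholds, lists of equal length, and score or tag number in place of fold. Alternatives chosen after seeing the data were the chromosome arms alone, an FDR of at most 5%, and wild-type peaks whose score stayed at or above 50 when multiplied by the ratio of mutant to wild-type tags.

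The overlap code was tested on simulated data. Of 3891 wild-type peaks, 1000 were given a simulated partner and 1000 were recovered as overlapped, while 0 of 500 simulated peaks placed apart were. Calculations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.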

Results

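Binding of the Bcd protein was compared between wild-type and zelda mutant embryos. Bcd is a homeodomain transcription factor made from mRNA laid down by the mother. The protein forms a gradient from the anterior pole and activates head and trunk patterning genes. Zelda is a maternally supplied zinc finger factor found throughout the early embryo, which is needed for the activation of many of the first zygotic genes. The comparison asks how the set of Bcd-bound regions differs when Zelda is missing. Each genotype was represented by 2 ChIP replicates and 2 input replicates, and by 1 deposited peak list. The wild-type ChIP held 39154546 tags after removal of duplicates and the mutant ChIP held 10060479.

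Bcd peaks were more numerous and longer in the wild-type list. It held 3891 peaks with a median length of 1970 bp, which together covered 9.70 Mb. The mutant list held 2650 peaks with a median length of 1279 bp, covering 4.03 Mb. Peaks on the chromosome arms numbered 2827 in wild type and 1870 in the mutant. The tags inside peaks made up 11.9% of the wild-type ChIP tags and 6.63% of the mutant ChIP tags, with a mean density (RPKM over the called regions) of 12.3 and 16.5. These sums follow the called length, which was shorter in the mutant. The authors' median fold enrichment was 5.11 in the wild-type list (interquartile range 4.31 to 6.37) and 3.97 in the mutant list (3.26 to 4.92). With an FDR of at most 5%, 1076 wild-type and 276 mutant peaks remained. The deeper wild-type library had more power to pass the same p cutoff, so the numbers of peaks do not by themselves compare the binding of the genotypes.

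Over the whole list, fewer than 50% of the wild-type Bcd regions overlapped a mutant region, though more than 50% did among stronger wild-type peaks. The share of mutant regions that overlapped a wild-type one was above or below 50% depending on the overlap asked for. Of the 3891 wild-type peaks, 1541 overlapped a mutant peak, or 39.6% (Wilson 95% interval 38.1 to 41.2). Random placement of the mutant peaks gave 6.20% on average and 7.38% at most in 1000 draws. Of the 2650 mutant peaks, 1650 overlapped a wild-type peak by at least 1 bp, or 62.3% (60.4 to 64.1), against 9.02% on average and 10.6% at most by random placement. The mutant share was 43.8% with a reciprocal overlap of 50% and 46.6% with summits within 200 bp. The 1 bp rule left 2350 wild-type-only and 1000 mutant-only peaks. On the chromosome arms the shares rose to 45.5% of wild-type peaks (43.6 to 47.3) and 74.4% of mutant peaks (72.4 to 76.4). Among mutant arm peaks with an FDR of at most 5%, 227 of 247 lay on a wild-type peak, or 91.9% (87.8 to 94.7). Among wild-type arm peaks with the same limit, 572 of 997 lay on a mutant peak, or 57.4% (54.3 to 60.4).

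Taken over all scores, the share of wild-type peaks with a mutant partner was lower on the heterochromatic and unplaced sequences than on the chromosome arms. Wild-type peaks lay on a mutant peak in 45.2% of cases on 2L, 46.5% on 2R, 41.2% on 3L, 48.7% on 3R and 44.7% on X. Differences between these arms were not tested. Chromosome 4 held only 15 wild-type peaks, of which 9 were shared. The heterochromatic scaffolds and the unplaced U sequences together held 297 wild-type peaks but 56 mutant peaks, and 33 of the 297 were shared, or 11.1% (8.02 to 15.2). Of the 56 mutant peaks, 34 were shared, or 60.7% (47.6 to 72.4). The unplaced Uextra sequences held 767 wild-type and 724 mutant peaks, which were 19.7% and 27.3% of their lists. Of these Uextra peaks, 29.1% of the wild-type ones (26.0 to 32.4) and 30.9% of the mutant ones (27.7 to 34.4) were shared. Most mutant peaks of Uextra thus had no wild-type partner over all scores. With a score of at least 200, 28 of 42 wild-type peaks of Uextra were shared (66.7%), against 56.3% on the arms and 22.4% on Het and U together. For mutant peaks at that score it was 64 of 97 on Uextra (66.0%), against 93.7% on the arms.

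**Figure D1:**
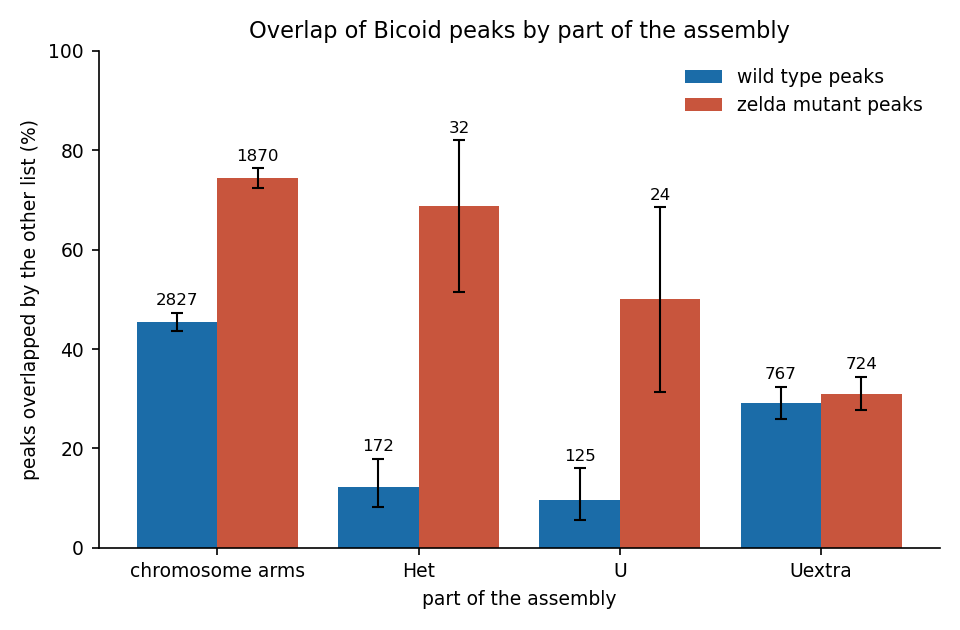
Share of Bcd peaks (y axis, percent) that overlap a peak of the other genotype's list by at least 1 bp, for the chromosome arms and the Het, U and Uextra sequences (x axis). Blue bars are wild-type peaks and red bars are mutant peaks, whiskers are Wilson 95% intervals and the labels on the bars are numbers of peaks; on the arms 45.5% of wild-type and 74.4% of mutant peaks are shared, against 12.2% of the wild-type peaks on Het.

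Shared Bcd regions were the stronger ones in both lists. On the arms, shared wild-type peaks had a median fold enrichment of 5.95 (interquartile range 4.89 to 7.25, 1285 peaks) and wild-type-only peaks one of 4.90 (4.18 to 6.16, 1542 peaks). The difference of 1.05 lay above all of 10000 random splits, which reached 0.40. In the mutant list, shared arm peaks had a median fold of 4.11 (3.42 to 5.17, 1392 peaks) and mutant-only arm peaks one of 3.54 (3.05 to 4.15, 478 peaks), a difference of 0.57 against 0.28 at most by random splits. A stronger peak is more likely to pass the p cutoff in both lists, whatever the genotypes. Shared wild-type arm peaks were also longer (median 2339 against 1986.5 bp), which eases an overlap of 1 bp. The random splits allow for neither, so these differences say nothing about Zelda. The share of wild-type arm peaks found in the mutant climbed from 28.3% (24.7 to 32.1) in the fifth with the lowest scores to 62.1% (58.1 to 66.0) in the fifth with the highest. Among mutant arm peaks the same shares were 50.8% (190 of 374) and 92.8% (347 of 374). A wild-type score of at least 1000 was reached by 214 arm peaks, of which 163 were shared and 51 were not. Several of the 51, on more than 1 arm, were alike in length, tag number, score and summit offset. Whether these are copies of 1 repeat was not tested, so the 51 need not be separate regions. The same peaks count among the 997 wild-type arm peaks with an FDR of at most 5%.

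**Figure D2:**
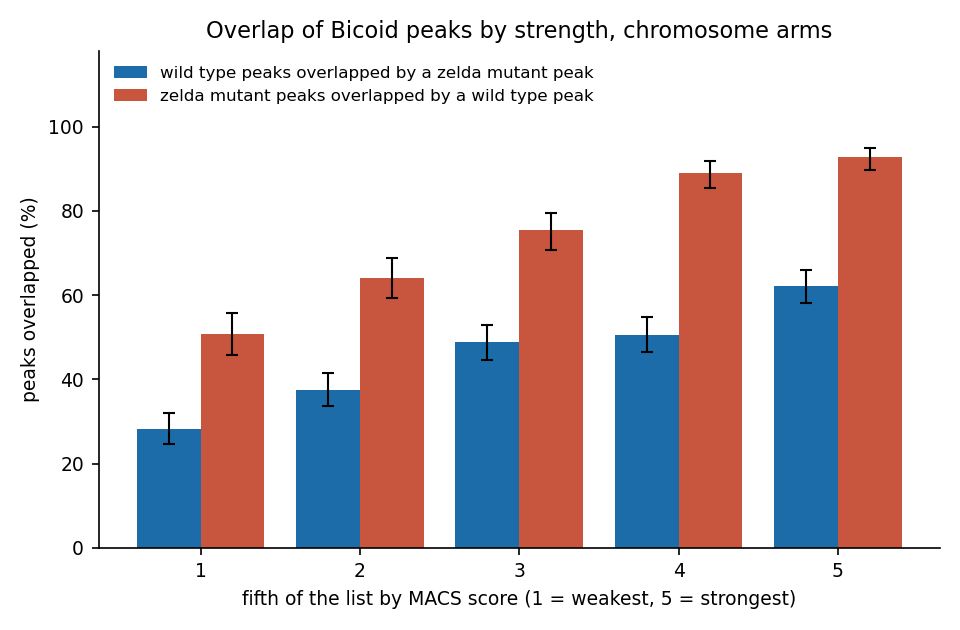
Share of Bcd peaks on the chromosome arms that overlap a peak of the other list (y axis, percent), for 5 bins of equal size of each list by MACS score (x axis, weakest to strongest). Blue bars are wild-type peaks and red bars are mutant peaks, with Wilson 95% intervals; in the strongest bin 92.8% of mutant peaks and 62.1% of wild-type peaks are shared.

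Equal numbers of the strongest arm peaks of each list overlapped only in part. Of the 50 wild-type arm peaks with the highest fold, 12 overlapped 1 of the 50 strongest mutant arm peaks, or 24.0% (14.3 to 37.4), while 37 overlapped some mutant peak. Of the 50 strongest mutant arm peaks, 48 overlapped some wild-type peak, or 96.0% (86.5 to 98.9). For the 500 strongest by fold, 182 wild-type peaks (36.4%, 32.3 to 40.7) overlapped a peak of the 500 strongest mutant ones. Ranked by score, the overlap was 16 of 50 and 195 of 500. Some mutant peak was overlapped by 45 of the 50 highest-scoring wild-type arm peaks, with an interval of 78.6 to 95.7%, and by 80 of the 100 highest-scoring ones, against 62 of 100 by fold.

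Where both lists held a single peak at a place, the summits lay close together. There were 1441 such pairs, with a median distance between summits of 45 bp, and 1159 pairs (80.4%) had summits within 200 bp. Of these pairs, 1187 lay on the arms. Across the arm pairs, the wild-type and mutant fold enrichments had a Spearman correlation of 0.55 and a Pearson correlation of 0.53; this is a correlation across peaks, which are not independent replicates. The scores had a Spearman correlation of 0.40. The mutant fold was the higher one in 122 of the 1187 arm pairs, with median folds of 5.86 in wild type and 4.10 in the mutant. The median tag density (RPKM over the called peak) went the other way, with 12.6 in wild type and 14.1 in the mutant. Each list came from its own ChIP and control libraries, with 1 list per genotype. The levels of fold in a pair therefore do not by themselves measure a change in binding. The mutant peak was shorter, with a median length 0.757 times that of its wild-type partner. A further 97 wild-type peaks each overlapped 2 or more mutant peaks, while 2 mutant peaks overlapped more than 1 wild-type peak.

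**Figure D3:**
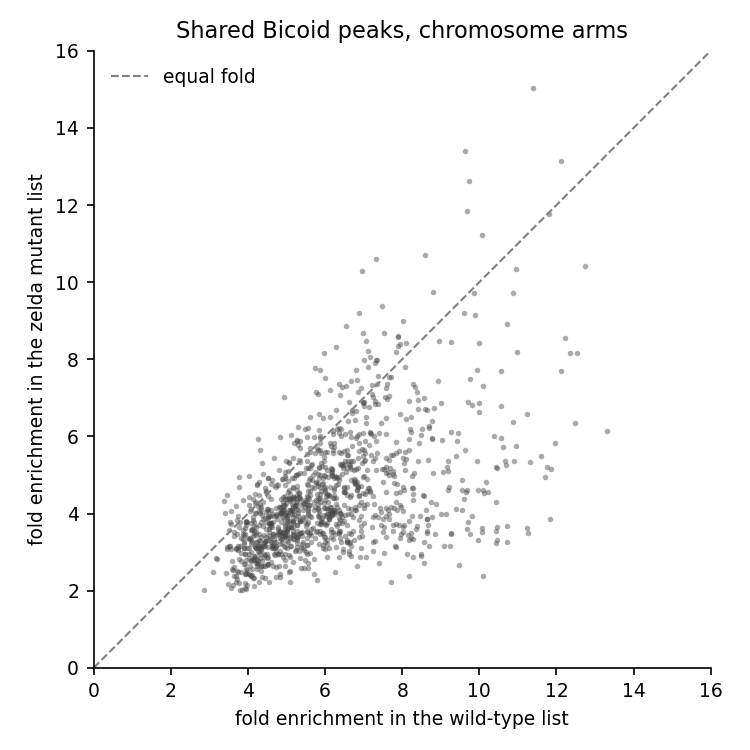
Fold enrichment over local background of 1187 Bcd peaks of the chromosome arms with 1 partner in the other list, in the wild-type list (x axis) and the mutant list (y axis). Each point is a peak pair and the dashed line marks equal values; the lists were scaled to different depths, and the Spearman correlation across peaks is 0.55.

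The 10 strongest shared regions had a fold enrichment of 12.1 to 13.3 in the wild-type list, and 6 of them lay on the X chromosome. The first was at 2L from 11454767 to 11457129, with a fold of 13.3 and 2044 tags (exact Poisson 95% interval 1956 to 2135). Its mutant partner from 11454934 to 11456319 had a fold of 6.13 and 258 tags. The peak at X from 20561279 to 20566175, with a fold of 13.1, overlapped 3 separate mutant peaks, the strongest with a fold of 5.93. The longest of the group spanned 10347 bp at 2R from 5859779 to 5870125, had a fold of 12.8 and 7940 tags, and covered 2 mutant peaks, the stronger with a fold of 8.46. No mutant summit lay within 200 bp of the wild-type summit of this 2R peak. On X, the peak from 18197136 to 18199421 had a fold of 12.7 and the strongest mutant partner of the group, with a fold of 10.4. The remaining members were 2L from 8808904 to 8812182, 3L from 8656818 to 8660876, and on X the peaks starting at 2330117, 7190395, 8547237 and 9583353. The strongest mutant partner of each had a fold between 6.35 and 8.61.

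The 10 strongest wild-type-only regions had folds of 10.9 to 12.8, and none of them overlapped a mutant peak. Their scores were 895 to 1697 and their tags 1039 to 3331, against 1359 to 3228 and 1222 to 7940 for the 10 strongest shared regions. The highest was at 2R from 20695490 to 20696992, with a fold of 12.8 and 1039 tags (977 to 1104). The nearest mutant peak lay 3.83 kb away. A further member of the group lay close by on 2R, from 20687686 to 20689325, with a fold of 10.9 and 1256 tags (1187 to 1327). On X the members were the peaks from 6942095 to 6944599 with a fold of 11.8, from 293176 to 294997 with a fold of 11.3, and from 11882203 to 11883897 with a fold of 11.2. On 3L they were the peaks from 8645762 to 8647649 with a fold of 11.6, from 5798840 to 5804548 with a fold of 11.4, and from 4756833 to 4758610 with a fold of 11.1. The last members were on 2R from 16213849 to 16216749 and on 3R from 27017901 to 27021120. The 3L peak from 5798840 to 5804548 had the most tags of the group, 3331 (3219 to 3446). The nearest mutant peak lay between 2.36 and 55.9 kb away, with a median of 14.1 kb.

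**Figure D4:**
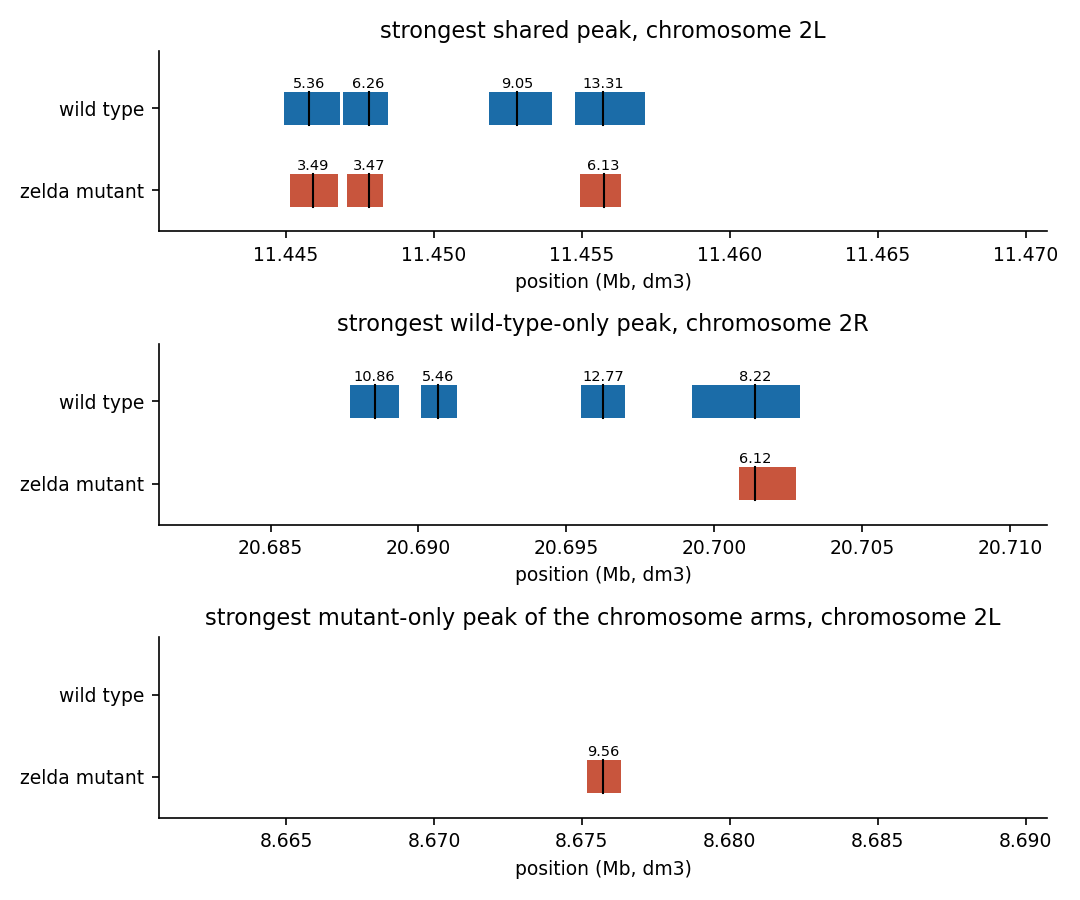
Positions on dm3 (x axis, Mb) of the Bcd peaks of the wild-type list (blue) and the mutant list (red) in windows centred on the strongest shared peak, the strongest wild-type-only peak and the strongest mutant-only peak of the chromosome arms. Black lines mark summits and the labels on the peaks are the authors' fold enrichments, such as 13.3 and 6.13 at the shared peak, 12.8 at the wild-type-only peak and 9.56 at the mutant-only peak.

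The 10 strongest mutant-only regions had folds of 7.91 to 9.82, and 7 of them lay on the unplaced Uextra sequences. The 3 on chromosome arms were at 2L from 8675166 to 8676317, with a fold of 9.56 and 263 tags (232 to 297), at 3R from 18882328 to 18883744, with a fold of 9.38 and 292 tags (259 to 327), and at 2R from 6438919 to 6441064, with a fold of 7.91 and 367 tags (330 to 407). The nearest wild-type peak was 73.4, 16.2 and 4.06 kb away. The FDR reached 9.34% within these 10 peaks. The Uextra member with the highest fold, 9.82, lay from 19603745 to 19604530 and held 199 tags (172 to 229).

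The 10 strongest Bcd regions of the mutant list on the arms by fold, chosen after their values were seen, all overlapped a wild-type peak. The first was at 3R from 4522909 to 4527183, with a fold of 15.0 in the mutant list and 11.4 in the wild-type list. Another of the 10 lay beside it on 3R, from 4517649 to 4521340, with folds of 12.6 and 9.73. On 2R the peak from 15546888 to 15550210 had folds of 13.4 and 9.63, and the peak from 5873149 to 5874560 had folds of 13.1 and 12.1. The wild-type fold was the higher one for the peaks starting at 19526206 on 2R (11.78 and 11.8) and 9703809 on 3R (11.33 and 11.81). The peaks were picked for a high mutant fold, which favours the mutant value. Across all arm pairs the mutant fold was higher in 122 of 1187.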

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

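The alternatives that used the arms alone, the FDR limit or the depth ratio were chosen after the data were seen; the others were set before. In each list shared peaks had the higher median under score, tag number, both other overlap rules and the arms alone. The wild-type share of shared peaks, 39.6%, became 29.9% with a reciprocal overlap of 50%, 31.8% with summits within 200 bp, 38.0% for the upper 50% of both lists by score, 51.6% for the upper 50% of wild type alone and 48.5% with lists of equal length. It became 45.5% on the arms, 55.9% for wild-type peaks with an FDR of at most 5%, 17.3% with that limit in both lists and 54.4% for wild-type peaks whose score kept 50 at the mutant depth. The wild-type share was thus above 50% where wild type alone was limited by its upper 50%, the FDR or the depth ratio. The mutant share, 62.3%, became in the same order 43.8%, 46.6%, 59.2%, 78.9%, 52.3%, 74.4%, 90.2%, 71.0% and 30.9%, so it was below 50% under the reciprocal rule, the summit rule and the depth ratio. Limiting the other list lowers a share by construction, since fewer peaks remain to be overlapped; for the other shifts the cause was not tested. The Spearman correlation of shared peaks fell from 0.57 for fold to 0.37 for score and 0.50 for tag number, and the cause was not tested. A fold of at least 9.32, 2 times the median of both lists, left 173 wild-type and 42 mutant peaks, and an FDR of at most 5% left 1076 and 276. Of the 10 strongest shared peaks, 5 lost their partner under the reciprocal rule and 1 under the summit rule, and the stricter rules cannot give a partner to the named unshared peaks. No paired analysis was possible because the files give 1 list per genotype and no values per replicate, so no replicate could be left out either. The planned gene list, gene position and motif results were not run, for want of a dm3 annotation and sequence among the material used. The mutant depth of 10060479 tags limits what can be called absent there.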

Other observations

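The tests below on depth, uniform enrichment, background range and the Het and U sequences were chosen after the result was seen; those on calls near the cutoff and on the places of mutant-only peaks were set before.

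On the arms there were 59 runs of at least 3 consecutive wild-type-only peaks with neighbouring summits no more than 10 kb apart, holding 192 of the 1542 wild-type-only peaks. Permuting the shared state within score deciles gave 44.2 runs on average and 30 to 61 in 1000 draws. The number of runs thus lay near the upper end of the permuted range, and how many draws reached it is not given. The longest run held 6 peaks over 28.7 kb at 2R from 358866 to 387550, with folds up to 6.79. Some of its peaks were alike in length, tag number and summit offset. A run of 4 peaks at 2R from 16198192 to 16219441 included 1 of the 10 strongest wild-type-only peaks. A run of 3 at 2R from 20687686 to 20696992 included the strongest of them, with a fold of 12.8, and the one starting at 20687686. A run of 3 at X from 293176 to 312015 included the one starting at 293176. X chromosome peaks made up 16.7% of wild-type arm peaks, yet 17 of the 50 strongest by fold (34.0%, 22.4 to 47.8) and 7 of the 50 strongest by score (14.0%, 6.95 to 26.2); in the mutant list they were 6 and 7 of 50. The interval by fold lay above 16.7%, while the interval by score held it. For the ranking by fold, random sets of 50 wild-type arm peaks held 0 to 20 X peaks, and how many sets reached 17 is not given.

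Lower depth of the mutant library does not account for all strong wild-type peaks of the arms that lack a mutant peak. When each wild-type score was recomputed at 0.257 times its depth, the ratio of filtered ChIP tags, from the score and the fold by the Poisson tail, 721 arm peaks still had at least 100, or 2 times the cutoff, and 40.6% of these (37.1 to 44.3) lacked a mutant peak; at 0.447, the ratio of the depths MACS scaled to, it was 43.7% of 1133 (40.8 to 46.6). A weaker enrichment shared by every peak in the mutant library stays open. The share with a partner rose with score, from 28.3% at scores of 50.05 to 76.14 to 62.1% at scores of 473.14 or more. It was 76.2% at a score of at least 1000. A partner was held by 45 of the 50 peaks with the highest scores, but by 37 of the 50 with the highest fold. A sharp form of this explanation, with at least 90% kept at the highest scores and at most 10% at the lowest, was not met. A rise with score alone does not decide the question. Scatter between libraries would give such a graded rise, and no replicate list measures it. Loss of Zelda at specific regions is a candidate explanation that cannot be told apart from other differences between the libraries, because the number of peak lists per genotype is 1. Several strong wild-type-only peaks, on more than 1 arm, were alike in length, tag number, score and summit offset. The named 3L peak from 5798840, with 5709 bp and 3331 tags, was close to them in length and tag number. The 40.6% and 43.7% without a mutant peak may thus count copies of 1 sequence more than once. Repeat content or copy number that differs between the 2 stocks therefore stays open on the arms too, and was not tested there.

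Of 546 pairs of neighbouring wild-type peaks of the arms with summits up to 5 kb apart, 66.1% were both shared or both unshared, against 51.1% on average and 59.5% at most when states were permuted within score deciles. Calls close to the cutoff stay open as an explanation. Among peaks with a score of at least 200, 103 pairs agreed in 55.3% of cases, inside the permuted range of 35.9 to 65.0%. That is the outcome this explanation asked for, but the range is wide for few pairs. The permuted states also kept the score deciles already, so the test does not decide the question. Pairs 5 to 10 kb apart agreed in 54.2% of cases (permuted range 39.8 to 57.2%) and 1056 pairs 10 to 50 kb apart in 51.5% (45.6 to 55.0%). The control background that MACS takes from up to 10 kb around a peak therefore cannot be told apart from any other short-range cause. A regulatory region that loses or keeps Bcd as a unit would look alike, and was not tested apart from these.

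Few wild-type peaks of the Het and U sequences had a mutant partner, while 34 of the 56 mutant peaks there had a wild-type one (60.7%). Weaker peaks on these sequences do not account for it: 11.1% were shared, while arm peaks matched on score were shared in 40.2% of cases on average and never under 29.6% in 10000 draws, and those matched on fold in 32.8% on average and never under 23.6%. Repeat content or copy number that differs between the 2 stocks stays open and cannot be told apart from a change in binding, as 0 columns of the files give control tags per peak. Mutant peaks of Uextra were shared in 30.9% of cases and matched mutant arm peaks in 67.6% on average. Wild-type peaks of Uextra were shared in 29.1% of cases and matched wild-type arm peaks in 35.1% on average, below the middle 95% of the draws (31.8 to 38.5%) but above the lowest (28.6%), and it was below all draws matched on fold (lowest 35.5%) or on score and fold together (lowest 30.6%).

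The hypothesis that mutant-only peaks mark binding moved to places beside wild-type peaks was tested on the arms. Of 478 such peaks, 96 lay within 2 kb of a wild-type peak (20.1%), against 7.97% on average and 12.3% at most for random places that touch no wild-type peak. A share above the highest of the random placements was the outcome set beforehand for this hypothesis, and it was met. Those placements do not allow for the crowding of peaks, which was not part of that rule. Wild-type arm peaks lay within 2 kb of another wild-type peak in 33.5% of cases, so the general crowding of peaks may be enough, and the test leaves the hypothesis open.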
